A study of Homo sapiens with 18 samples.

How the data were processed

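The series holds 18 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from WTC11 human induced pluripotent stem cells that were differentiated towards atrial cardiomyocytes. Per the labels' protocols, each replicate was a separate 6-well plate whose wells were pooled after dissociation and fixed with formaldehyde. Each library therefore counted as 1 biological replicate. TBX5, a T-box transcription factor of the heart, was profiled in 12 libraries through a biotin-accepting tag placed at the start of the endogenous gene, at day 11 (D11, 2 libraries), day 20 (D20, 6 libraries) and day 45 (D45, 4 libraries). CTCF, a zinc-finger protein that holds chromatin loops and domain borders in place, was profiled at D20 in 6 libraries, with 2 libraries each of cells with both TBX5 alleles intact (WT), with 1 allele disrupted (Het) and with none intact (Null). Which protein a library profiled was read from the series' design text, in which the mutant genotypes belong to the CTCF libraries.

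Each file was a list of peaks called in 1 library, not on pooled replicates. The build was hg38, and the tools named were Bowtie2, SAMtools, bedtools, MACS2 and deepTools, per the submitters' processing notes, with no versions given. The deposited lists carry, for each peak, an integer score, the authors' fold enrichment (a ratio), and the −log10 p-value and −log10 q-value that the authors' peak caller gave, with the summit position as an offset. Every deposited −log10 q-value was above 1.30, so the lists end at a q-value of 0.05. Gaps in the authors' peak numbering showed that at least 0.403% to 9.07% of the called peaks of a library had been taken out before deposit. The filter is not given in the sources used here. The files hold no read counts, so sequencing depth is unknown, and a list can be longer through depth or enrichment as well as through binding. The −log10 q-values were used to rank peaks within a list (as a percentile), to shorten lists and as a stricter threshold, and no score, fold or significance value was compared between libraries.

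The prefixes of the authors' peak names put the libraries into 3 sets. All 6 D20 TBX5 libraries belonged to 1 set, all D11 and D45 TBX5 libraries to another, and all CTCF libraries to the third. D11 and D45 could thus be compared within a set, and D20 could not be compared with either day within a set. The CTCF genotypes shared a set.

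Peaks of the 12 TBX5 libraries that shared at least 1 bp were merged into loci, and those of the 6 CTCF libraries likewise. Mitochondrial peaks stayed in the peak numbers and locus counts and were left out of distances to genes. A library had a locus when at least 1 of its peaks fell in it. Loci in 2 or more libraries of a day are called reproducible at that day. CTCF loci with a peak in both WT libraries and in neither Null library are called lost, and the opposite kind gained. Genes were the 20037 protein-coding genes of the GRCh38.p14 RefSeq table on standard chromosomes. That table gives gene starts and ends without strand or exons, so distances were taken to either annotated end of a gene where the transcription start site had been planned, and exon or intron is not given. No genome sequence was used here, and the 2 planned motif analyses, the T-box motif at TBX5 summits and the CTCF motif at CTCF summits, were not run.

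Peak numbers (log2) and per-library shares were compared with two-sided exact permutation tests, and the CTCF genotypes with an exact trend test over the 90 arrangements of the libraries on 2, 1 or 0 intact alleles. For each of these measures the p-values of the 3 day comparisons were adjusted together by the Benjamini-Hochberg method. Single loci were compared between days by two-sided Fisher's exact tests on libraries with and without a peak, adjusted over all loci tested. The 19 gene lists (398 entries, 341 of 344 symbols matched) were tested by Fisher's exact test for genes with a locus within 50 kb of an annotated end, one-sided for TBX5 and two-sided for CTCF, adjusted over the lists. Overlap of TBX5 and CTCF loci was set against 1000 random placements of each TBX5 locus 10 to 200 kb away. Neighbouring genes can share a locus, loci share libraries, and neither are independent replicates, so Fisher p-values over genes or loci measure enrichment within these libraries only. The lists, most tests and most alternatives were fixed before the data were examined, and those added later are named where they are used.

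Named TBX5 genes and loci were, by a fixed rule, up to 4 members of each list with a peak within 50 kb in the most libraries, the 10 loci found in the most libraries with the highest mean percentile, up to 5 loci per day comparison and direction with the smallest p, and a few genes named in advance, among them NPPA, NPPB, TBX5 and NKX2-5. Some items that this rule takes are not reported here. Named CTCF loci were the 5 lost and 5 gained loci with the highest mean percentile, and up to 10 list genes per direction nearest to a lost or gained locus. The mitochondrial locus and a locus on a Y-chromosome patch sequence were left out of these names.

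The alternatives were a −log10 q-value of at least 5, lists shortened to the shortest list (209 TBX5 peaks, 66452 CTCF peaks), loci built from summits within 100 bp, peaks that cover 50% of a locus, autosomes alone, other windows and recurrence limits, matched random lists, the replicate number as a block, and leaving out each library. The 50% alternative had a second clause that every peak meets, which was dropped. The locus tests were tested on simulated data with the real peak rates. For D20 against D45, 400 of 400 simulated loci present in every library of 1 day and none of the other were called among 2950 tested, 0 of 200 were called among 2792 tested, and no unchanged locus was called. For D11 against D20 none of the 200 or 400 such loci was called among 4212 and 4340 tested. A planted list with 12 of 20 genes near a locus was called and none of 18 random lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.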

Results

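TBX5 binding was mapped in 12 ChIP-seq libraries of WTC11-derived cells on the way to atrial cardiomyocytes, at D11 (n = 2), D20 (n = 6) and D45 (n = 4), and CTCF binding in 6 libraries at D20, with 2 each from WT, Het and Null cells that carry 2, 1 or 0 intact TBX5 alleles. The series asks how human chromatin responds to the dose of TBX5, a gene linked to heart disease. Each library is represented by the list of peaks its authors called in it, on hg38 coordinates. The TBX5 lists held between 209 and 7355 peaks and the CTCF lists between 66452 and 92639. Read depth is unknown, so a peak that is missing from a list was not detected there and is not shown to be absent.

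The first comparison asks how TBX5 occupancy develops over the differentiation. Most TBX5 loci found later were already found at D11, and the D11 lists were the longest. The D11 libraries had 4180 and 7355 peaks, a mean of 5767.5 ± 2245 (SD, n = 2), against 1153 ± 664 (SD, n = 6) at D20 and 1021 ± 755 (SD, n = 4) at D45. Merging gave 8902 loci, of which 4257 occurred in 2 or more libraries. At D11, 3566 loci were reproducible, at D20 1598 and at D45 992, and 807 loci were reproducible at all 3 days. Of the 1763 loci reproducible at D20 or D45, 93.4% had a peak in at least 1 D11 library, and only 116 had none. In the other direction, 1348 of the D11 loci were found in no later library. Peak number was 5.72-fold lower at D20 than at D11, with both D11 libraries above all 6 D20 libraries (exact permutation p = 0.0357, adjusted p = 0.107 over the 3 comparisons), so the difference did not pass the adjusted threshold. It was 7.20-fold lower at D45 than at D11, within 1 library set, where the exact test on 2 and 4 libraries gave p = 0.133 and a single split of the 15 is worth 0.0667. D45 and D20 differed by 1.26-fold, less than the spread between replicates (exact permutation p = 0.657), and the direction turned without D45 replicate 2, the shortest list (log2 difference -0.333 with it and 0.295 without). Leaving out that library also moved the log2 difference of D45 and D11 from -2.85 to -2.22. With every list shortened to 209 peaks, 172 loci were reproducible at D11, 261 at D20 and 219 at D45, but 2 libraries cannot share more than 209 loci then while 4 or 6 libraries can, so these counts do not compare the days. Without D45 replicate 1 or replicate 4, 636 or 522 loci were reproducible at D45.

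**Figure D1:**
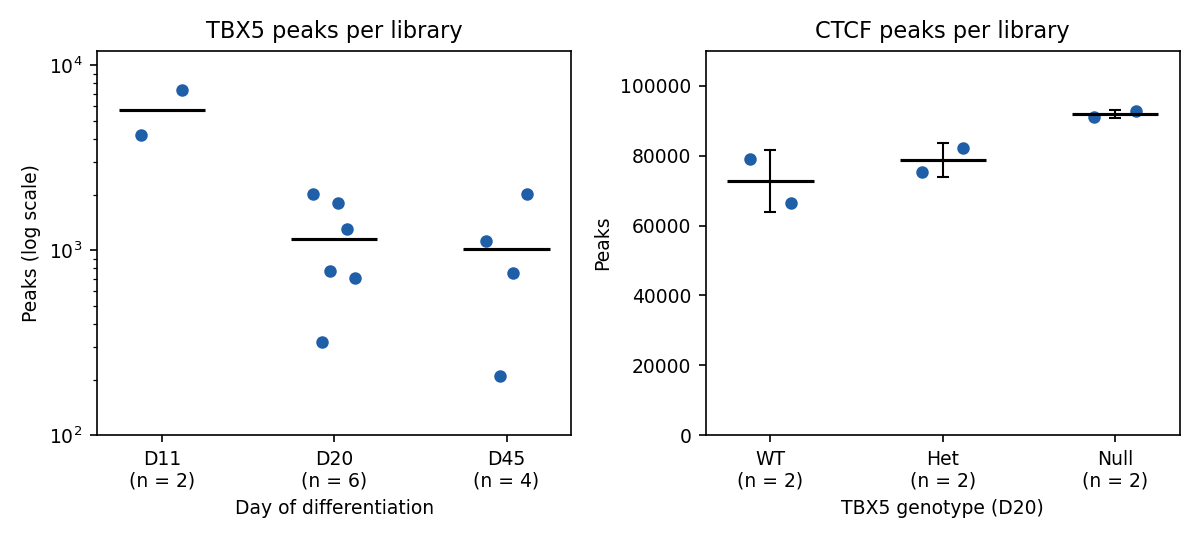
Peaks per library for TBX5 by day (left, log scale) and for CTCF by TBX5 genotype at D20 (right, linear scale); points are libraries, horizontal bars are means and whiskers in the right panel are 1 SD. Both D11 libraries, at 4180 and 7355 peaks, lie above all later TBX5 libraries, and both Null libraries, at 91151 and 92639 peaks, lie above all other CTCF libraries.

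A core of 104 nuclear TBX5 loci had a peak in all 12 libraries. The strongest by mean percentile lay on chromosome 2 at 240236409-240237261, 95751 bp from the nearest annotated end of a protein-coding gene, that of OTOS, with a mean within-library percentile of 99.5. The next lay inside HSPB7, which encodes a small heat-shock protein abundant in the heart, at 1:16017835-16018511, 1083 bp from a gene end and at percentile 99.3. The other 8 of the strongest 10 had their nearest gene ends at UACA, WDFY3 (inside the gene), TBX3, HOXB1, OPN4, GATB, PAX9 (inside the neighbouring gene SLC25A21) and ATP2A2. The first 3 of the 10, near OTOS, HSPB7 and UACA, also overlapped a CTCF locus of both WT libraries. The locus near TBX3, a T-box repressor of the conduction system, lay 115266 bp from the gene at 12:114799441-114800159, and a second locus in all 12 libraries lay 19736 bp from it. ATP2A2 encodes the cardiac calcium pump of the sarcoplasmic reticulum, and its locus at 12:110252627-110253634 lay 26982 bp from the gene.

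Heart gene lists were enriched near TBX5 loci. With loci from any 2 of the 12 libraries, 21.3% of other protein-coding genes had a locus within 50 kb of an end, against 57.7% of sarcomere genes (15 of 26, odds ratio 5.05, one-sided Fisher's exact test with adjusted p = 0.00108), 61.1% of atrial identity genes (11 of 18, odds ratio 5.81, adjusted p = 0.00272), 52.9% of calcium handling genes (9 of 17, odds ratio 4.16, adjusted p = 0.0257), 47.4% of ion channel and gap junction genes (9 of 19, odds ratio 3.33, adjusted p = 0.0388) and 44% of cardiac transcription factors (11 of 25, odds ratio 2.91, adjusted p = 0.0388). The lists overlap, and 13 of the 18 atrial and 16 of the 25 transcription factor entries stand in another list as well. By Fisher's exact test, the cardiac transcription factors no longer passed without D11 replicate 1 (adjusted p = 0.110) or D11 replicate 2 (adjusted p = 0.0571), and the ion channels without D11 replicate 1 (adjusted p = 0.0949), while the heart signalling list passed without D45 replicate 4 (adjusted p = 0.0461). The ion channels also no longer passed with a 100 kb window (Fisher's exact test, adjusted p = 0.148) or against random lists matched on gene length and gene ends (permutation, adjusted p = 0.0662), nor the calcium handling genes with loci of 1 library included (Fisher's exact test, adjusted p = 0.0707). With a 10 kb window the sarcomere and atrial lists were the 2 that passed, and both passed under all 21 alternatives run. In the same exact test, heart signalling ligands (9 of 21, adjusted p = 0.0682), congenital heart disease genes (14 of 41, adjusted p = 0.108), ventricular identity genes (5 of 11, adjusted p = 0.152) and genes at atrial fibrillation loci (11 of 37, adjusted p = 0.279) did not pass. Of the 21 alternatives, the atrial fibrillation and signalling lists passed in 5 each, the ventricular list in 3 and the congenital heart disease list in 2. With each locus given to its nearest gene end alone, all 4 passed, the atrial fibrillation list at an adjusted p of 8.18e-06 (its range over the alternatives ended at 0.339), and so did the fibroblast and matrix list (Fisher's exact test, odds ratio 3.07, adjusted p = 0.0408). Among the lists of other cell types, near counts were 4 of 10 epicardial, 6 of 20 fibroblast and matrix, 2 of 9 smooth muscle, 5 of 15 endothelial, 3 of 9 pluripotency, 5 of 20 liver, 6 of 19 skeletal muscle and 0 of 20 neuronal genes, with 4 of 19 housekeeping and 3 of 39 HOX genes, and with the 50 kb window none of these lists passed (adjusted p of 0.279 or more).

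The named members show where these loci lie. NPPA and NPPB, the neighbouring genes of the atrial and B-type natriuretic peptides, shared a locus found in all 12 libraries at 1:11882698-11883527, 34915 bp from NPPA and 23753 bp from NPPB. GJA5, the gap junction protein connexin 40, had a locus in all 12 libraries 6782 bp away at 1:147748693-147749417. HCN4, a pacemaker channel, had one 5588 bp away at 15:73374546-73375160, and KCNH2, a repolarising potassium channel, one 709 bp away at 7:150979030-150979745, which also lay within the window of the endothelial gene NOS3. The sarcomere genes MYL2 and LDB3 had loci in all 12 libraries 7125 and 1562 bp away. TNNT2, cardiac troponin T, had a locus on its annotated end at 1:201377551-201378138 in 11 libraries, and the same locus was the one assigned to TNNI1. MYH7 and MYH6, the myosin heavy chain neighbours on chromosome 14, shared a locus at 14:23438134-23438573 found in 7 libraries. RYR2, the calcium release channel, had a locus inside the gene in 10 libraries. TBX5 had a locus 40085 bp from its own end, at 12:114448527-114449154, in 11 libraries. TBX2, IRX4, BMP5 and HOXB1 each had a locus in all 12, MEIS2 and FBLN1 in 11, and STARD10 and ACTN3 in 10. NKX2-5, a core cardiac transcription factor, had a peak within 50 kb in both D11 and 3 of 4 D45 libraries and in 0 of 6 D20 libraries. CACNA1C, the L-type calcium channel, had the opposite arrangement, with a peak on its annotated end at 12:1970495-1970874 in 5 of 6 D20 libraries and in none at D11 or D45. The NKX2-5 count joins 8 loci, of which the most recurrent was in 2 D11 and 2 D45 libraries. Both arrangements follow the library set as well as the day, and the 2 cannot be told apart. ELAVL4, the neuronal gene with the most libraries, had peaks in 2, and LIN28A, a pluripotency gene, in the 2 D11 libraries alone.

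Day by day, the sarcomere and atrial lists passed at every day. Sarcomere genes stood at 13 of 26 at D11 (odds ratio 4.70, Fisher's exact test with adjusted p = 0.00150), 15 of 26 at D20 (odds ratio 14.1, adjusted p = 9.06e-09) and 12 of 26 at D45 (odds ratio 12.7, adjusted p = 3.45e-07), while the share of other genes with a locus went from 17.5% to 8.82% to 6.33%. Atrial identity genes stood at 11, 7 and 7 of 18 (Fisher's exact test, adjusted p = 0.000874, 0.00540 and 0.000686). Calcium handling genes passed at D11 (8 of 17) and D20 (6 of 17) and stood at 3 of 17 at D45 (Fisher's exact test, adjusted p = 0.215). Ion channels and gap junctions passed at D11 (8 of 19) and D45 (7 of 19), and cardiac transcription factors at D11 (10 of 25) and D45 (7 of 25), with both at an adjusted p of 0.0844 at D20. Genes at atrial fibrillation loci passed at D45 alone among the days (9 of 37, odds ratio 4.74, Fisher's exact test with adjusted p = 0.00198), and heart signalling genes at D11 (9 of 21) and D45 (5 of 21). Whether an odds ratio differed between days was not tested.

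**Figure D2:**
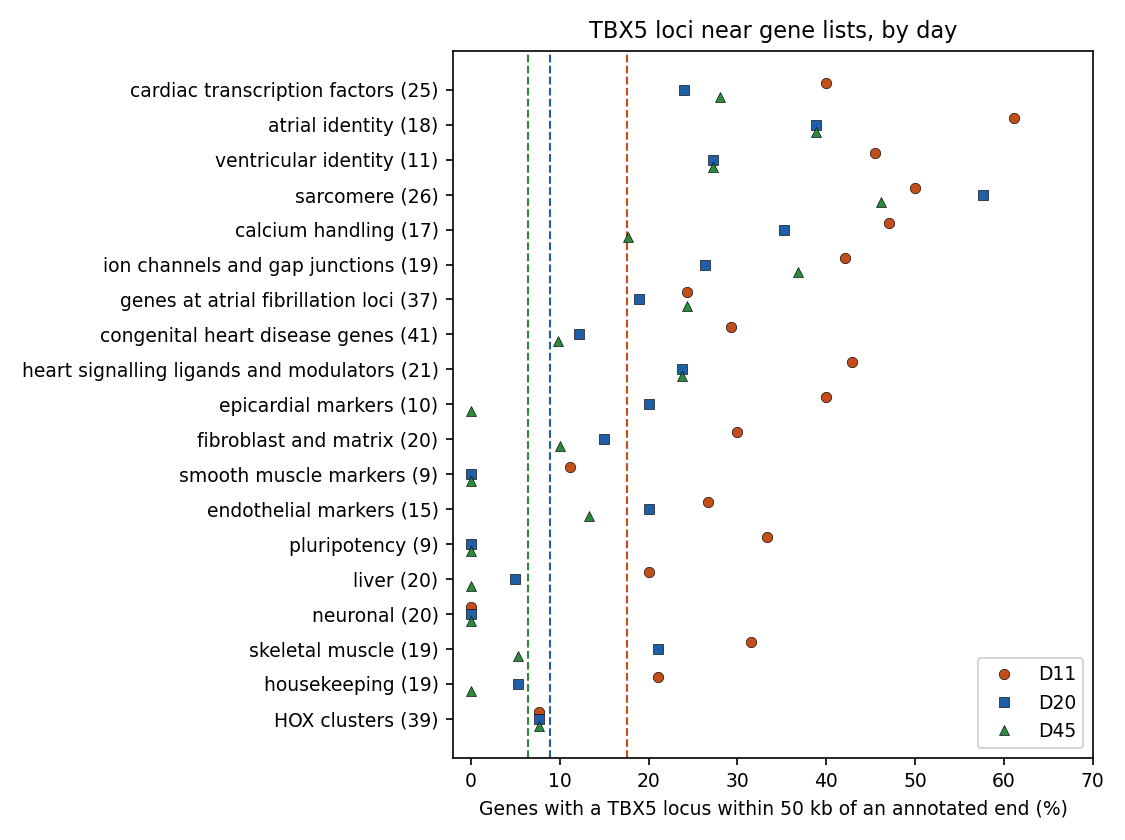
Percent of the genes of each list (number tested in parentheses) with a reproducible TBX5 locus within 50 kb of an annotated end, at D11 (circles), D20 (squares) and D45 (triangles); dashed lines give the mean share among genes outside the lists at each day. Sarcomere genes stand at 50.0% at D11, 57.7% at D20 and 46.2% at D45, and neuronal genes at 0 on each day.

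No single locus passed the adjusted test in the 2 day comparisons made by locus, and D11 against D45 was not tested by locus. Between D20 and D45, 1982 loci were tested by Fisher's exact test and 0 passed (smallest adjusted p = 0.726), with 46 at an unadjusted p under 0.05, of which 37 were found more often at D20. Between D11 and D20, 4006 loci were tested by Fisher's exact test and 0 passed (smallest adjusted p = 0.0902), with 1586 at an unadjusted p under 0.05, of which 1575 were found more often at D11. Here the test cannot give a p below 0.0357. The 1586 became 24 with lists of equal length, where 2 D11 lists cannot share more than 209 loci. The count of 46 became 108 without D20 replicate 2, 84 without D20 replicate 6 and 30 without D45 replicate 3. Among loci tied at the smallest p towards D20, the 5 with the highest mean percentile were the same in both comparisons and had a peak in 6 of 6 D20 libraries and in no D11 or D45 library. They lay at the end of the tubulin cofactor gene TBCE (1:235367028-235367538, mean percentile 98.3), in FITM1 (14:24131224-24131762, percentile 96.9), 57385 bp from KLF13 (15:31268892-31269450), in KIF26B (1:245327823-245328269) and in INPP5D (2:233193676-233194067). Loci found in both D11 libraries and in no D20 library were led by 1 near PTH2R (2:208552818-208553417), 1 in CDH11 (16:65105314-65106013), 1 in RGS6 nearest to the end of DPF3, 1 in CCDC3 and 1 in MTHFD1L. Towards D45 the named loci were 1 in ARHGAP26, 1 in LHFPL6 and 3 on unlocalised or unplaced contigs, each in 3 of 4 D45 and 0 of 6 D20 libraries (Fisher's exact p = 0.0333). Each was also found in at least 1 D11 library, and those in ARHGAP26 and LHFPL6 in both. They were thus missing from the D20 library set alone and are not shown to be gained at D45. No D20 list held a peak on such contigs, while every D11 and D45 list did, so contig peaks followed the library set, and D20 cannot be told apart from its set.

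Few TBX5 summits lay at gene ends, though the share expected by random placement was not computed. The share within 1 kb of an annotated end was 9.20% ± 3.73 (SD, n = 2) at D11, 6.46% ± 0.877 (SD, n = 6) at D20 and 8.69% ± 3.80 (SD, n = 4) at D45. Neither D20 against D11 (exact permutation p = 0.143, adjusted p = 0.293) nor D45 against D20 (exact permutation p = 0.195, adjusted p = 0.293) differed by more than the spread between replicates. The D20 minus D11 difference of -2.74 points was -0.100 without D11 replicate 2 and -5.38 without D11 replicate 1. Without D45 replicate 2, D45 lay 3.98 percentage points above D20 (exact permutation p = 0.0119). With lists of equal length both differences changed sign, to -1.79 points for D45 minus D20 (exact permutation p = 0.110) and 1.58 points for D20 minus D11 (exact permutation p = 0.357). The planned T-box motif share at these summits was not computed.

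The second set of comparisons asks how CTCF binding responds to the TBX5 dose at D20. CTCF lists were longer with fewer intact TBX5 alleles. WT libraries had 72770.5 ± 8936 peaks, Het libraries 78721.5 ± 4956 and Null libraries 91895 ± 1052 (SD, n = 2 each), or 1.13-fold more per lost allele (exact permutation trend p = 0.0444 over 90 arrangements). WT and Null alone differed by 1.27-fold, where the exact permutation p of 0.333 is the smallest that 2 against 2 can give. The trend did not pass when WT replicate 2 or either Null library was left out (exact permutation p = 0.133 each). Without a Het library, or with the replicate number as a block, the exact permutation p cannot go below 0.0667 and 0.0556, so these settings could not pass. The Null lists also held narrower peaks, the median width rising by 34.5 bp per intact allele (exact permutation p = 0.0222, the smallest of this design). This width test was not among those planned. Widths were not compared at equal list length, so the width trend does not tell TBX5 dose from list length.

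Most CTCF loci were found in every genotype. Of 106138 loci, 57823 (54.5%) had a peak in all 6 libraries. Lost loci numbered 770 and gained loci 9558. Of the lost loci, 169 were in both Het libraries, 294 in 1 and 307 in neither. Of the gained loci, 2454 were in both, 3077 in 1 and 4027 in neither. Both kinds were weak, with median within-library percentiles of 20.8 (lost) and 21.0 (gained), against 63.3 for loci in all 6. With every list shortened to 66452 peaks, which by itself brings the directions close in number, 2323 loci were lost and 2783 gained. These 5106 loci were the most of any of the 45 ways to set 2 CTCF libraries against 2 others (next 4304, the WT pair against Het replicate 1 with Null replicate 1), a count made after the data were seen. The counts also rest on single libraries, since a class defined by fewer libraries is met more easily. Lost and gained loci numbered 1514 and 18925 without WT replicate 1, 4478 and 11273 without WT replicate 2, 1263 and 17601 without Null replicate 1, and 1382 and 16401 without Null replicate 2. Among the 15 pairs of libraries, the Null pair had the most loci found in that pair alone (4027, against 859 in the next pair, WT replicate 1 with Null replicate 2, and 307 in the WT pair; with lists of equal length the order of Null and WT turned, to 686 and 984), and the WT pair the most loci missing from that pair alone (2454). The pair of WT replicate 2 and Het replicate 1, which differ in genotype, missed 2416. Summed over the 3 genotype pairs, 4503 loci were found in a pair alone (exact permutation p = 0.133 over 15 matchings) and 2847 were missing from a pair alone (exact permutation p = 0.0667, the smallest possible).

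The 5 strongest lost loci lay at 20:25986984-25987930, far from any gene end, in GFPT2 (5:180341590-180342248), in SLC25A20 (3:48881886-48882358), in CSMD1 (8:3928890-3929474) and in RBM47 (4:40541419-40542205). All but that in CSMD1 were found in both Het libraries. The strongest gained locus lay on an annotated end of CIMIP2C (2:26561997-26562947, percentile 72.1), followed by loci at ZNF559 (19:9323640-9324339), in OPA3 (19:45553351-45553984), at 20:30290308-30290721 and in RBFOX1 (16:7405094-7405611). None of these 10 lay within 10 kb of a reproducible D20 TBX5 locus. CTCF peak sets of the same genotype were somewhat more alike, with a mean Jaccard index (shared over covered base pairs) of 0.725 within and 0.696 between genotypes. The difference of 0.0297 gave a one-sided exact permutation p of 0.133, where 15 matchings cannot go below 0.0667. The least similar same-genotype pair was the WT pair, at 0.673. The planned CTCF motif share was not computed.

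TBX5 and CTCF loci overlapped more than local placement gave. Of 1597 reproducible D20 TBX5 loci on standard chromosomes, 298 (18.7%) shared at least 1 bp with a CTCF locus of both WT libraries, against 5.03% ± 0.543 (SD over 1000 placements), a ratio of 3.71 (permutation p = 0.000999, the smallest that 1000 placements can give). The same share was 17.9% of 3561 loci at D11 and 24.7% of 987 at D45. Per library, 17.8% ± 0.824 of D20 peaks (SD, n = 6) and 22.1% ± 4.27 of D45 peaks (SD, n = 4) overlapped such a locus, a difference with an exact permutation p of 0.0381 that did not pass adjustment over the 3 day comparisons (adjusted p = 0.114). This per-library test was not among those planned. The random placements were not matched on open chromatin. The ratio of 3.71 therefore does not tell a link of TBX5 and CTCF from peaks of both lying in open regions.

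CTCF loci lost in Null cells lay close to TBX5 loci more often than gained loci did. Within 10 kb of a reproducible D20 TBX5 locus were 54 of 770 lost loci (7.01%, exact 95% interval 5.31 to 9.05%), 146 of 9558 gained loci (1.53%, 1.29 to 1.79%) and 2.05% of the loci in all 6 libraries (odds ratio of lost against gained 4.86, Fisher's exact p = 1.97e-17). The contrast was sharpest at the TBX5 loci themselves, in a setting added after the data were seen, where 32 lost loci (4.16%) and 4 gained loci (0.0418%) overlapped one (odds ratio 104, Fisher's exact p = 2.00e-32). It weakened to 31.2 within 1 kb and 2.65 within 50 kb. Of the 32, 5 were in both Het libraries, 17 in 1 and 10 in neither. They included loci inside PRDM16 (1:3327965-3328453), RBM24 (6:17289696-17290058), MAPK4 (18:50695509-50695860) and VGLL4 (3:11560169-11560555), and the one at 15:70438759-70439142 lay in the strong TBX5 locus near UACA described above, all named after their values were seen. The 10 kb odds ratio was 2.60 without WT replicate 1 and 3.01 without Null replicate 1. Of the 45 ways to set 2 CTCF libraries against 2 others, 8 gave an odds ratio at least as far from 1 as WT against Null, and in all 8 the side with more intact TBX5 alleles had the loci nearer to TBX5. The same held in 30 of the 35 splits with unequal allele numbers. In all 8, that side also held WT replicate 1 or Het replicate 2, the libraries with CTCF peaks at the most D20 TBX5 loci (26.9% and 21.9%). With equal allele numbers the odds ratio reached 3.07, for WT replicate 1 with Null replicate 2 against WT replicate 2 with Null replicate 1. The splits therefore do not tell TBX5 dose from single libraries.

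Counted per library, the same sites showed a smaller difference between genotypes. A CTCF peak was found at 26.9% and 17.7% of the 1597 D20 TBX5 loci in the WT libraries, at 16.6% and 21.9% in the Het libraries and at 18.4% and 19.0% in the Null libraries, with no trend beyond the spread between replicates (1.80 points per intact allele, exact permutation p = 0.378). Without WT replicate 1 the slope was -0.353. With CTCF lists of equal length, a setting also added after the data were seen, the shares were 18.8% ± 1.59 in WT, 15.0% ± 1.86 in Het and 13.3% ± 0.0886 in Null libraries (SD, n = 2 each), a slope of 2.79 points per intact allele (exact permutation p = 0.0222, the smallest of 90 arrangements). The mean was lowest in Null libraries both ways, and the trend passed the test with lists of equal length alone. Shortening left WT replicate 2, the shortest list, at 283 TBX5 loci with a CTCF peak. It took Null replicate 1 from 294 to 213 and Null replicate 2 from 304 to 211. The longer Null lists lose the most peaks in this setting, so its trend does not tell TBX5 dose from list length.

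**Figure D3:**
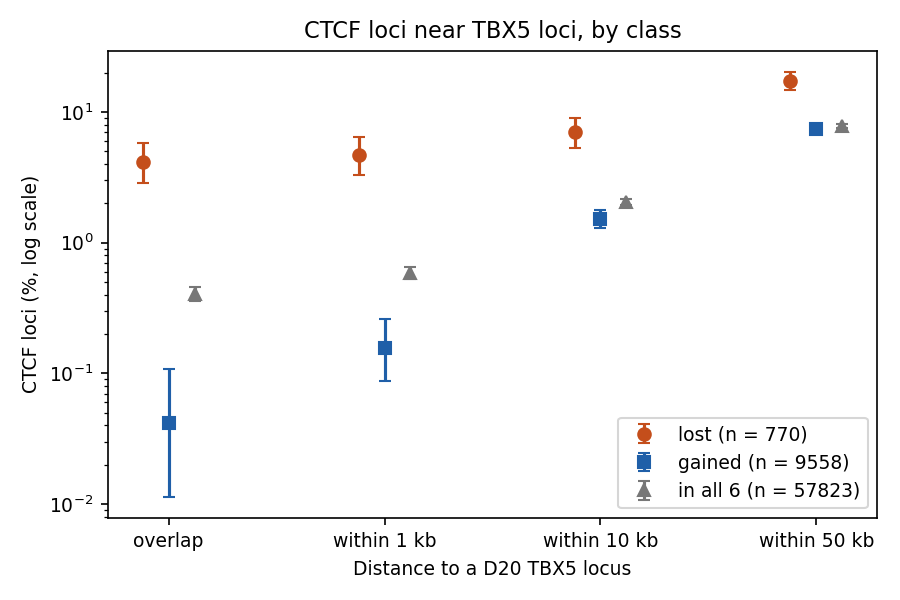
Percent of lost, gained and constant (in all 6 libraries) CTCF loci that overlap a reproducible D20 TBX5 locus or lie within 1, 10 or 50 kb of one (log scale); whiskers are exact 95% binomial intervals over loci, which cover counting error only. Lost loci stand at 4.16% for overlap, against 0.0418% of gained loci.

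**Figure D4:**
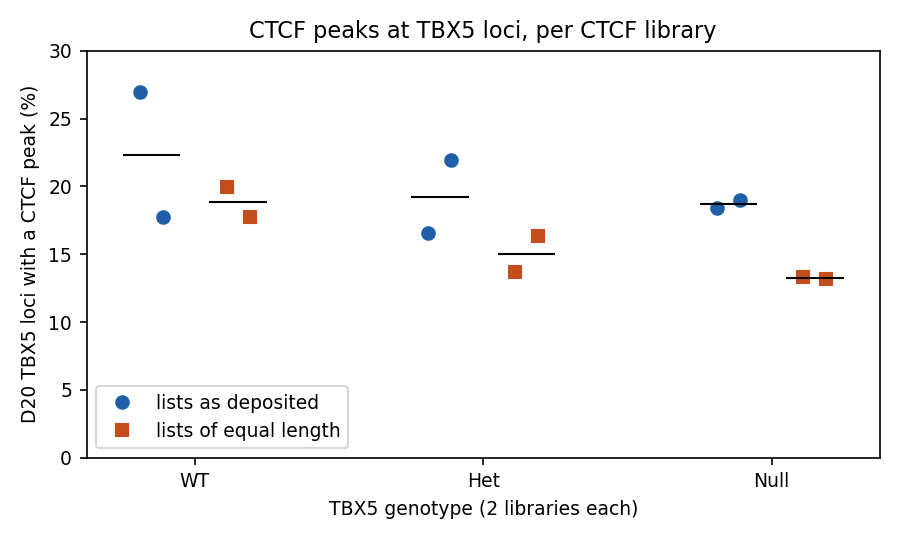
Percent of the 1597 reproducible D20 TBX5 loci with a CTCF peak in each CTCF library, by TBX5 genotype, with lists as deposited (circles) and with lists of equal length (squares); bars are means of 2 libraries. With equal lengths both WT libraries, at 20.0% and 17.7%, lie above all other libraries, and as deposited the genotypes overlap.

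Near the gene lists, atrial identity genes stood out among lost loci and HOX genes among gained loci. A lost locus lay within 50 kb of 5 of 18 atrial identity genes (27.8%, against 4.76% of other genes with any CTCF locus in reach, odds ratio 7.69, two-sided Fisher's exact test with adjusted p = 0.0240). These were NPPA, KCNJ3, NR2F1, TBX5 and MYL4. NR2F1 and MYL4 also had a gained locus, 9225 and 42353 bp away. A gained locus lay within 50 kb of 10 of 18 atrial identity genes (55.6%, against 48.6% of other genes). The lost locus at NPPA (1:11847698-11848236) covered an annotated end of the gene and was found in 1 Het library. That 1380 bp from KCNJ3, a subunit of the acetylcholine-gated atrial potassium channel (2:154700075-154700504), was in both. The one at TBX5 (12:114396043-114397490) lay inside the gene whose alleles the genotypes alter, was in both Het libraries, and was accompanied by a gained locus in Null cells at 12:114405210-114405732. None of these 5 lost loci lay within 10 kb of a reproducible D20 TBX5 locus. By Fisher's exact test, the list no longer passed with lists of equal length (odds ratio 2.14, adjusted p = 0.470), without WT replicate 2 (adjusted p = 0.0644) or without Null replicate 1 (adjusted p = 0.142). Other list genes nearest to a lost locus were NKX2-5 (5:173227644-173228708, 3401 bp away and in both Het libraries), GJC1, BMP7, CSRP3, PAX3 and SMAD6. No other list passed for lost loci in the 6 libraries, among them sarcomere (3 of 26) and cardiac transcription factors (3 of 24), and calcium handling genes had none of 16. Sarcomere genes did pass with lists of equal length, without WT replicate 2 and without Null replicate 2, and 4 lists passed without WT replicate 2, 3 without Null replicate 2 and 0 without Null replicate 1.

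Gained loci lay within 50 kb of 38 of 39 HOX genes, against 48.5% of other genes (odds ratio 40.4, Fisher's exact test with adjusted p = 5.54e-10). HOX genes sit in 4 clusters, so these genes share their loci. With 1 member per cluster, a setting added after the data were seen, all 4 members left lay near a gained locus, but with 4 members Fisher's exact test cannot give a p below 0.0556, so this setting could not pass. With lists of equal length and all members the list passed (Fisher's exact test, odds ratio 6.13, adjusted p = 9.47e-07). The gained loci nearest to list genes covered an annotated end of ERBB4, HOXB8, MEIS1, RPS6, SNAP25 and WT1 and lay within 323 bp of TNNT2, HOXD11, HOXA13 and PRRX1. Those at TNNT2 and PRRX1 were found in 1 Het library and the other 8 in none. They were weak, from percentile 4.92 at HOXB8 to 27.6 at RPS6. No other list passed for gained loci, with 16 of 24 cardiac transcription factors, 14 of 26 sarcomere genes and 4 of 18 skeletal muscle genes near one (Fisher's exact test, adjusted p = 0.304 for the last). Endothelial markers joined the HOX genes without Null replicate 2.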

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

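The tests of list length, of weak detection and of the library set, the splits at equal list length and the allele counts of the splits were chosen after the result was seen. All 12 TBX5 libraries had peaks on the mitochondrial genome, which are counted among the peaks but not described in the report, covering 10595 to 16559 bp, against 2 of 6 CTCF libraries, in which they covered 259 and 806 bp (two-sided Fisher's exact p = 0.00490, a test that was not planned).

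CTCF loci lost in Null cells lay within 10 kb of a D20 TBX5 locus more often than gained loci did. Percentile within a list and distance to genes, as measured here, do not account for it. Percentiles are ranks in lists of unlike length, so lost and gained loci of like percentile can differ in strength, which stays open. Lost and gained loci were alike in median percentile (20.8 and 21.0), with an odds ratio of 4.92 (95% interval 3.57 to 6.80) within equal bins of percentile, and they differed in median distance to a gene end (36170.5 and 26944.5 bp), with an odds ratio of 5.04 (3.64 to 6.96) within classes of distance. Chance assignment of libraries is not excluded: 8 of the 45 splits of 2 against 2 libraries gave an odds ratio as far from 1 as the real one of 4.89 (computed with a small-count correction), the highest other being 7.96 for WT replicate 1 with Het replicate 2 against Het replicate 1 with Null replicate 2, although in all 8, and in 30 of the 35 splits with unequal numbers of intact alleles, the side with more of them had the nearer loci. In all 8, that side also held WT replicate 1 or Het replicate 2. Differences between single libraries that do not follow genotype, and a dependence of weak CTCF peaks at TBX5 loci on TBX5, both stay open.

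Gained CTCF loci outnumbered lost ones 12.4 to 1 with lists as deposited. With 66452 peaks taken from every library the ratio was 1.20, but equal lengths held it between 1.00 and 1.77 in all 45 splits, so this does not tell technical list length from wider CTCF occupancy in Null cells, and both stay open without read depth. Of the 45 splits as deposited, 2 reached 9558 loci, the real one and WT replicate 2 with Het replicate 1 against Null (9816, the highest other). This share lies narrowly under the 0.05 set in advance for a random choice of libraries. But the other split exceeded the real one, and both set the Null libraries, with the longest lists, against others. The count thus does not tell genotype from list length, and a random choice of libraries is not firmly excluded. At equal length, 1 of the 45 splits, the real one, had as many as 5106 loci in both directions together (highest other 4304). This share is under 0.05, but it is the lowest that 45 splits can give, for a count chosen after the data were seen. The planned matching and Jaccard tests, with lists as deposited, gave exact permutation p of 0.0667 to 0.133 and could not go below 0.0667. Chance is therefore not firmly excluded for that count. Whether such loci follow genotype beyond list length stays a hypothesis from 2 libraries per genotype.

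In all, 21 TBX5 loci had a peak in at least 5 D20 libraries and in no D11 or D45 library, 11 of them in all 6, and 6 loci had the opposite arrangement. Besides those already named they lay at SIRT2 (19:38899406-38899808), NMRAL1 (16:4476305-4476665), MARCHF8, MRPL23 and DSCAM, among others chosen after their values were seen, and 0 of the 21 overlapped a CTCF locus. Weak detection at D20 does not account for them: their median D20 percentile of 74.9 was 23.8 above that of the 40 loci found in as many D20 libraries and in 1 to 3 others (51.1, two-sided permutation p = 1.00e-04 across loci, which are not independent). The size of this gap rests on the loci compared. Loci found in as many D20 libraries and in 6 others had a median of 87.2. All 453 loci in 5 or more D20 libraries had 73.3, near that of the 21 D20-only loci. Chance is not excluded, since 5 of 100 splits of the 12 libraries gave as many such loci, and the highest other gave 88, several times the real count, which points to a structure of the libraries; the 4 other splits each held both D11 libraries and 5 of the 6 longest lists on the side with the loci. For these 21 loci the day and the library set cannot be told apart, since all D20 libraries and no others came from 1 set, and both stay open.

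For TBX5 loci between D20 and D45, 0 loci passed in the real split by Fisher's exact test, a count that all 100 splits reach by necessity (highest other 0), so they say nothing about it. At an unadjusted p under 0.05, 25 of 100 splits had at least 46 loci, the highest other having 220, and chance is not excluded for that count.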

How the results depend on the processing

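The settings with gene spans, length-matched lists, 1 member per cluster, crossed Het numbers, overlap by 1 bp, and left-out CTCF libraries for the near-TBX5, list and similarity results, and all alternatives for locus counts per day and for TBX5 loci with a CTCF peak, were chosen after seeing the data. CTCF loci near TBX5 loci kept their direction and passed under all 14 alternatives (odds ratios 2.60 to 104). TBX5 overlap with CTCF passed under all 10, against random placements that do not match open chromatin. The 0 calls between days held under all 16 (D20 against D45) and 14 (D11 against D20). Of these, at least 1 and 3 could not pass (the replicate block, and 1 D11 library). For D11 against D20 the test cannot give a p below 0.0357, and 0 of 400 simulated changed loci were called. The 0 calls there say little about stability under any alternative. The sarcomere and atrial TBX5 lists passed under all 21. The cause was not tested for any change below, except that equal lengths and left-out libraries leave fewer peaks or samples. The motif analyses were not run. Unknown read depth limits all counts of absent peaks.

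With lists of equal length, reproducible TBX5 loci numbered 172 at D11, 261 at D20 and 219 at D45, where D11, with 2 libraries, cannot exceed 209. The 1586 loci between D11 and D20 at an unadjusted p under 0.05 became 24, and 11 with loci in 3 or more libraries, which leaves out loci of the 2 D11 libraries alone. Lost and gained CTCF loci then numbered 2323 and 2783, those in Null alone 686, and 3 lists passed for lost loci, 1 of them HOX genes as a depletion (odds ratio 0, Fisher's exact test, adjusted p = 0.0177). The trend of TBX5 loci with a CTCF peak was 2.79 points. With summits within 100 bp, 1212 loci were lost. The TBX5 lists that passed, 5 in the report, were 2 with a 10 kb window, 10 with each locus given to its nearest gene end (fibroblast and matrix genes among them) and 8 with loci in 4 or more libraries. With 1 member per cluster, 0 lists passed for gained CTCF loci, but the HOX list, with 4 members, could not pass.

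Leaving out 1 library at a time, the D20 against D11 log2 peak number ranged from -2.92 to -2.11, D45 against D11 from -3.31 to -2.22 and D45 against D20 from -0.793 to 0.295, the TBX5 lists that passed from 3 to 6, reproducible D45 loci from 522 to 985, and the gene-end share of D45 minus D20 from 1.09 to 3.98 points and of D20 minus D11 from -5.38 to -0.100 points. For CTCF, the trend per intact allele ranged from -0.23 to -0.12, lost loci from 771 to 4478, gained loci from 9567 to 18925 and loci in Null alone from 4236 to 10769. Lists passing ranged from 0 to 4 for lost and from 1 to 2 for gained loci, and for lost loci near HOX genes the odds ratio, 0 in the report, ranged from 0 to 2.60 and was 2.38 without WT replicate 2 (Fisher's exact test, adjusted p = 0.0410).

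The replicate numbers were also used as a block, although correlations of deviations between libraries of like number ran from -0.124 to 0.0749 and the pairing is not stated. With this block, D20 against D11 gave -2.79 (exact permutation p = 0.500) and the CTCF trend -0.17 (exact permutation p = 0.111, and 0.0556 with the Het numbers crossed), where 0.500 and 0.0556 are the smallest possible and neither could pass. Within number 1 alone 6654 CTCF loci were lost and 18188 gained, within number 2 alone 2323 and 28279.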

Other observations

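The tests per gene list and at D45 in the last paragraph were chosen after the result was seen. TBX5 loci also lay near genes outside the heart lists that passed. MYH1 and MYH2, skeletal myosin heavy chain neighbours, shared a locus at 17:10545155-10545763 found in 8 libraries. COL6A3, a matrix collagen, had a locus in 7 libraries at 2:237291342-237291753, and SFRP1 and SMAD7, modulators of WNT and BMP signalling, each had a locus in 7 libraries. ACTB, a housekeeping gene, had a locus 24276 bp away in 6 libraries.

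Summits of both proteins lay inside genes at similar rates. For TBX5 the share was 53.8% ± 0.972 (SD, n = 2) at D11, 54.1% ± 1.21 (SD, n = 6) at D20 and 53.4% ± 3.32 (SD, n = 4) at D45. For CTCF it was 53.3% ± 0.453 in WT, 52.9% ± 0.547 in Het and 53.5% ± 0.792 in Null libraries (SD, n = 2 each). CTCF summits within 1 kb of a gene end made up 15.5% ± 0.746, 15.3% ± 0.224 and 14.8% ± 0.0250 in WT, Het and Null libraries, a slope of 0.348 points per intact allele (exact permutation p = 0.156, n = 2 each). This trend test was not among those planned.

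The hypothesis that TBX5 may be retained preferentially near heart genes was tested on the reproducible D11 loci. Near the 97 genes of the cardiac transcription factor, atrial, ventricular, sarcomere, calcium handling and ion channel lists, 41 of 77 D11 loci (53.2%) were reproducible at D20, against 1372 of 3484 others (39.4%). Within equal bins of D11 percentile the odds ratio was 1.42 (95% interval 0.708 to 2.85), so a preference was not shown once strength was matched. At D45, 50.6% of the loci near heart genes and 25.3% of the others were kept, with an odds ratio of 3.77 (1.90 to 7.49) within the same bins. By list at D20, the odds ratio was 4.21 (1.04 to 17.1) for sarcomere genes, with 15 of 20 loci kept, and the interval held 1 for the other 8 lists examined. Lower shares than that of the other loci were kept near congenital heart disease genes (4 of 22, odds ratio 0.467, 0.125 to 1.75), heart signalling genes (5 of 17, odds ratio 0.757) and atrial identity genes (8 of 22, odds ratio 0.892). Loci of 1 library are not independent, and whether D20 and D45 differ was not tested. D11 and D45 shared a library set and D20 did not, so day and set cannot be told apart in these retention values.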
